A study of Mus musculus with 4 samples.

How the data were processed

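RNA sequencing of 4 mouse samples was analysed, 1 per group: CD137+ and PDGFRα+ adipocyte progenitors, each with PBS or 1 µM dexamethasone. RNA was taken with Trizol and libraries were made with the Illumina TruSeq RNA kit, per the labels' protocols. Cufflinks, Cuffdiff and the mouse genome build mm10 are named in the submitters' processing notes, without versions. The aligner and the gene annotation are not given in the sources used here.

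The authors deposited 3 tables, each with 2 columns of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 per library, per the file headers. The same tables hold the authors' log2 ratio of the columns, and the deposited p-value and q-value of each gene, per the file headers. The deposited log2 ratios differed from ratios recomputed from the FPKM by at most 3.92e-05. Where a library was listed at 0 the ratio was a placeholder, in 55, 195 and 194 genes of the CD137+, PDGFRα+ and between-type tables. Such 0 values may be failed estimates. The authors' q-values rest on 1 library per group and are quoted only as theirs. Each gene's higher value was never below 0.386 FPKM in the 3 tables, so genes under a low bound are not listed. Every per-sample column was mapped to a sample by its name, and 0 were left over. The 6 columns held 6 different sets of values although the labels give 4 samples. The sheet titles number the libraries of 1 label differently, so a label in 2 tables was not taken for the same library.

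FPKM scales each library by its total, so a library in which a few transcripts take a large share has lower values for the rest. The 10 highest genes took between 8.94% and 14.1% of summed FPKM in the 6 libraries. The median log2 difference over genes at 1 FPKM or more in both libraries was 0.06 in the CD137+ table (11660 genes), 0.28 in the PDGFRα+ table (11512) and -0.24 in the between-type table (11349). Depth is unknown: FPKM low in each library showed no steps of whole reads, so no counting interval is given.

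The labels give 1 sample per group, and the sources used here do not say whether columns of the same label are replicates, so no test between conditions was made. Differences are on the scale of log2(FPKM + 1), which understates those of low genes, and a gene was counted as apart at 2-fold or more with at least 1 FPKM in the higher library. A list's members "measured" are those at 1 FPKM or more in the higher library. For each of 31 gene lists the median difference was set against 10000 random lists of the same size, drawn from 10 bins of mean expression, and called outside beyond the 2.5 and 97.5 percentiles. This describes the libraries compared and is no p-value. The lymphocyte list had 0, 1 and 0 measured members in the 3 tables, under the minimum of 3, so 30 lists were used.

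The size rule, the lists, the rule for named genes and the other settings listed below were set before the data were examined. The named genes were Nr3c1, Tead1, Pdgfra, Tnfrsf9, Pparg, Adipoq, Ucp1, Fkbp5 and Tsc22d3 whatever their values. To these came the 6 genes with the highest and the 6 with the lowest difference per comparison at 5 FPKM or more, without predicted genes. Up to 4 members of each list described, those with the largest differences, were added. A gene named in 1 comparison may be given for another, and such values were chosen by the first comparison's rule.

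The results were recomputed with pseudocounts of 0.1 and 5 FPKM, no minimum and a minimum of 10 FPKM, thresholds of 1.5-fold and 4-fold, rescaling by the median difference or the upper quartile, the authors' deposited log2 ratio, random lists without matching, and Spearman's correlation. The exchange of DEX columns between tables was added after the columns were seen to differ. Values from different tables were first brought to a median difference of 0. Gene identifiers were looked up in the GENCODE M21 annotation of GRCm38 (mm10). At least 99.8% of identifiers in each table were found, and of these 97.3% had a deposited locus that held the annotated gene or ended within 5000 bases of it. Where a symbol belonged to several identifiers (11, 11 and 9 symbols), the one with the higher mean was used.

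The scripts were tested on simulated data with noise of 0.15 log2 units. Among 14208, 15009 and 14679 genes of the 3 tables, 96%, 97% and 99% of genes changed 2.8-fold were recovered, 100% of those changed 8-fold, and 0 unchanged genes were called. The changed genes had a mean of 5 FPKM or more, and all genes had the same noise. Real columns of the same label had log2 ratios with an SD of 0.57 (CD137+) and 0.78 (PDGFRα+) at 10 FPKM or more. These rates thus test the scripts and not how the size rule behaves on these data. Of 200 random lists 5%, 3% and 5.5% fell outside the range, and 100% of lists shifted by 0.3 log2 units were recovered. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.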

Results

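RNA was sequenced from cultured adipocyte progenitors of C57BL/6 mice. CD137+ cells were sorted for the tumour necrosis factor receptor family member CD137 (gene Tnfrsf9), which has been used to mark precursors of beige, heat-producing adipocytes. PDGFRα+ cells (also named CD140+ in the labels) were sorted for the platelet-derived growth factor receptor Pdgfra, a general marker of adipose progenitors. Both kinds were sorted with magnetic beads from the fat depots named SAT or VAT, grown, given an adipogenic cocktail, and then given PBS or 1 µM dexamethasone (DEX), a synthetic glucocorticoid. The labels do not say which kind came from which depot. They give 4 samples, 1 per group, so no difference below has a replicate check and no p-value was computed. By the title of the series, the study asked whether glucocorticoids steer PDGFRα+ progenitors towards white adipocytes through methylation at Tead1.

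The deposited values are FPKM in 3 tables of 2 columns each, 1 table for DEX and PBS in each cell type and 1 for the DEX libraries of both cell types. The 6 libraries listed between 14208 and 15009 genes, of which 11971 to 12465 stood at 1 FPKM or more. Summed FPKM lay between 430997 and 449283. Sequencing depth is unknown, because low FPKM values showed no steps of whole reads. The tables were made separately, so a level set beside one from another table is only approximate.

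Columns with the same label held different values in different tables. The 2 columns labelled PDGFRα+ DEX differed by at least 2-fold at 2603 genes once their median difference was set to 0 (Pearson r = 0.891 across genes, which are not independent replicates). The 2 columns labelled CD137+ DEX differed at 1149 genes (r = 0.937). The PDGFRα+ DEX column of the between-type table differed from PDGFRα+ PBS at only 21 genes (r = 0.994). By the library numbers in the sheet titles, PBS shares its number with the DEX column of the same table in CD137+ cells (126 genes apart) and with that of the between-type table in PDGFRα+ cells (21 genes apart). The DEX columns with the other number were 1482 and 2771 genes from PBS. Each column was therefore kept as a library of its own, named by its label and its table, and none were averaged.

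**Figure D1:**
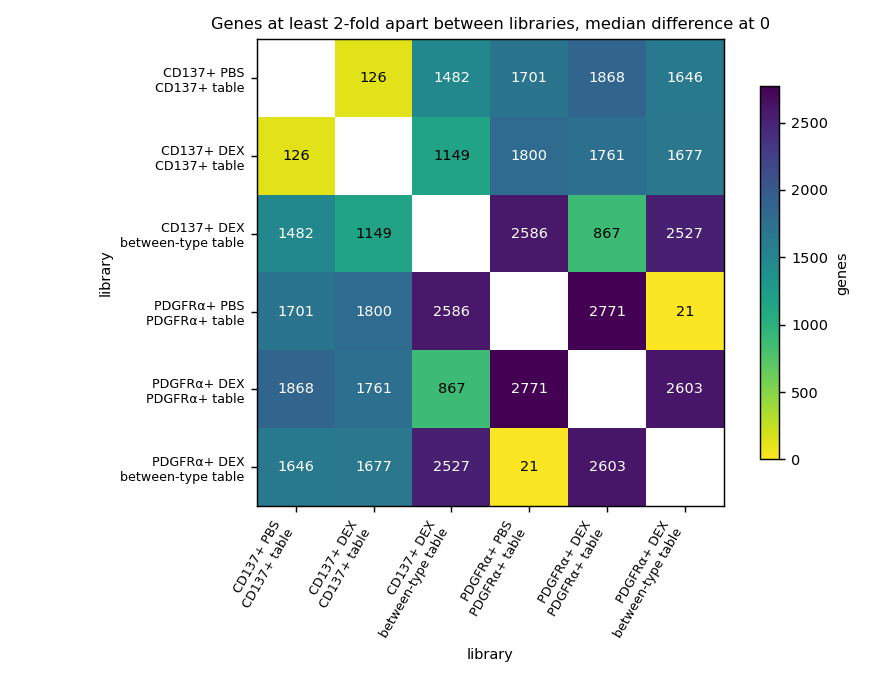
Number of genes at least 2-fold apart (colour and printed value) between each pair of the 6 deposited columns, named on both axes by cell type, label and table, after the median difference of each pair was set to 0. PDGFRα+ PBS and the PDGFRα+ DEX column of the between-type table are 21 genes apart, and the 2 PDGFRα+ DEX columns are 2603 apart.

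Genes that glucocorticoids are known to induce went against the labels in the PDGFRα+ table. Tsc22d3 (GILZ), a direct target of the receptor, stood at 113 FPKM with PBS and 30.2 FPKM in the library labelled DEX. Zbtb16 stood at 24.2 and 3.69 FPKM and Klf15 at 18.8 and 1.61 FPKM, both being transcription factors induced by glucocorticoids in many tissues. Fkbp5, which encodes a co-chaperone of the receptor, stood at 64.7 and 35.8 FPKM. In the CD137+ table Fkbp5 was nearly equal (68.1 with PBS, 66.2 with DEX) and Tsc22d3 was lower with DEX (76.1 and 38.5 FPKM). The libraries are therefore called "the library labelled DEX" below, and each direction is that of the label. Nr3c1, the glucocorticoid receptor itself (ENSMUSG00000024431, GRCm38 chromosome 18, 39410545 to 39519421), was present in all 6 libraries at 15.1 to 30.5 FPKM. The mRNA of the sorting marker Tnfrsf9 did not follow the labels of cell type either. It was not listed in the CD137+ table and stood at 0.161 FPKM in the other CD137+ library, against 1.62 to 4.81 FPKM in the PDGFRα+ libraries, whereas Pdgfra followed them in the between-type table (67.7 FPKM in CD137+ and 146 FPKM in PDGFRα+ cells) but not with PBS (164 and 136.7 FPKM, across tables). Cell types are thus named by their labels as well.

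**Figure D2:**
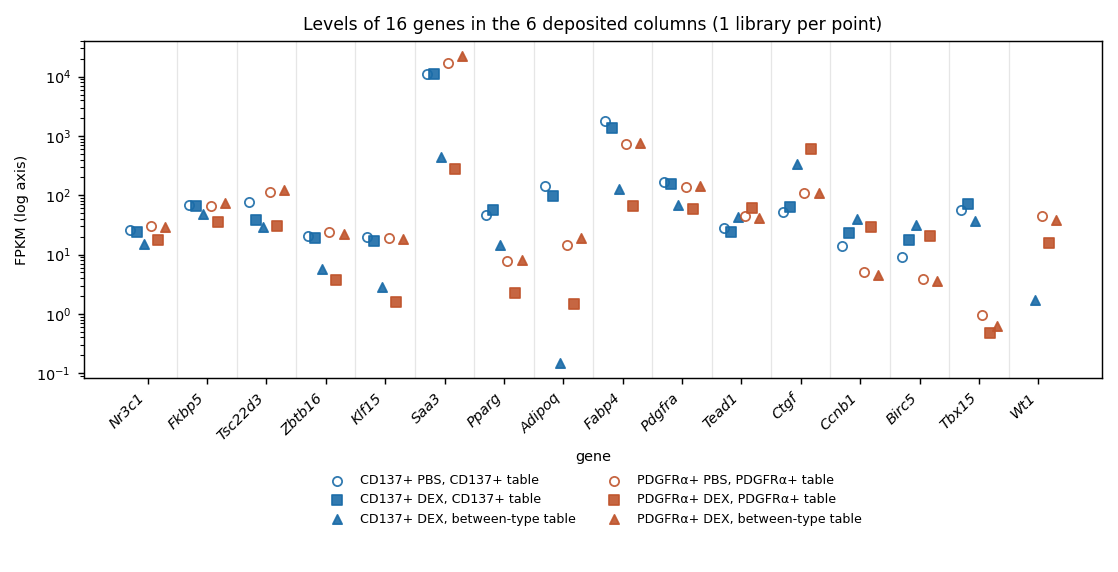
FPKM (log axis) of 16 genes in the 6 deposited columns, 1 point per library; open circles are PBS, squares the DEX columns of the CD137+ and PDGFRα+ tables, triangles the DEX columns of the between-type table. Klf15 stands at 18.8 FPKM in PDGFRα+ PBS, 1.61 in the DEX column of the same table and 18.6 in that of the between-type table; Wt1 was not listed in the CD137+ table.

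In CD137+ cells, the library labelled DEX held far more mRNA of immediate early genes, the transcription factors switched on within minutes of a stimulus. Fos stood at 3.54 FPKM with PBS and 148 FPKM in the library labelled DEX, Egr1 at 3.95 and 149.8, and Fosb at 0.392 and 62.8. The orphan receptor gene Nr4a1 (1.17 and 29.8 FPKM), the neutrophil chemokine Cxcl1 (23.8 and 277) and the prostaglandin synthase Ptgs2 (1.12 and 12.7) followed. Some lipid synthesis genes were lower, such as fatty acid synthase, Fasn, at 324 and 149 FPKM. In all, 58 genes were at least 2-fold higher and 70 at least 2-fold lower among 12304 genes at 1 FPKM or more.

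Of 15 measured immediate early and heat shock genes, 8 were at least 2-fold higher, none were 2-fold lower, and the median log2 difference was 1.32. Of 25 inflammatory cytokines and chemokines 5 were higher and none lower (median 0.46), among them Il6 (1.76 and 14.7 FPKM) and the monocyte attractant Ccl2 (229 and 496). Interferon response genes had a median of 0.62, but only Isg15, a ubiquitin-like modifier, passed 2-fold (65.9 and 144 FPKM) among 28. The 33 cell cycle genes had a median of 0.59 with no member past 2-fold, as in Cdc20 (10.7 and 21.4 FPKM) and Ccna2 (12.4 and 23.3). Of 19 stress response genes 2 were higher (median 0.32): Trib3 (4.41 and 18.1 FPKM) and Chac1 (0.623 and 4.23), both known targets of the integrated stress response.

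Adipocyte genes lay lower together, though by less than 2-fold. The 28 general adipocyte genes had a median of -0.40 with no member past 2-fold: the hormone gene Adipoq stood at 145 and 95.7 FPKM, the triglyceride lipase Pnpla2 at 186 and 102, and the adipsin gene Cfd at 37.5 and 19.6. Of 20 lipogenesis genes 3 were 2-fold lower (median -0.50): Fasn, the carbohydrate-sensing factor Mlxipl (21.1 and 9.58 FPKM) and Pnpla3 (3.66 and 0.970). Pparg, the master regulator of adipocyte differentiation, did not follow (46.6 and 56.6 FPKM). The 33 glucocorticoid-induced genes had a median of -0.11. The phosphatase gene Dusp1 was the 1 member past 2-fold, at 39.2 and 135 FPKM. Smaller negative medians were those of thermogenic genes (-0.18 over 14, such as the beta adrenergic receptor Adrb3 at 19.2 and 11.6 FPKM), lipolysis and fatty acid oxidation genes (-0.12 over 19), cholesterol synthesis genes (-0.10 over 22) and fibroblast matrix genes (-0.07 over 34).

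Markers of other cells and structural RNAs also differed. Of 12 endothelial markers 3 were 2-fold lower (median -0.62), Emcn (4.42 and 0.785 FPKM), Pecam1 (5.12 and 1.78) and Cdh5 (5.07 and 1.89). Mural and smooth muscle markers had a median of -0.29 with none of 11 past 2-fold, and skeletal muscle markers of -0.55 with 1 of 7 lower. The 6 named genes with the lowest ratios were structural RNAs, led by Rn7sk at 15.01 and 0.609 FPKM. The other 5 were lower in the PDGFRα+ library labelled DEX too, such as Rmrp (5.44 and 1.59 FPKM). Rn7s1, Rn7s2 and Rn18s-rs5 have near-identical copies in the genome, so their values are uncertain. Saa3, an acute-phase protein gene, took 2.53% of all FPKM with PBS and 2.43% in the library labelled DEX. Tead1, a Hippo pathway transcription factor (ENSMUSG00000055320, GRCm38 chromosome 7, 112679318 to 112906807), stood at 28.3 and 23.6 FPKM. Of 37 Hippo pathway genes and TEAD targets, Cyr61, a matricellular target of YAP and TEAD, was the 1 member past 2-fold (68.7 and 319 FPKM). Pdgfra was level (164 and 154 FPKM), and Tnfrsf9 and the thermogenic gene Ucp1 were not listed.

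Of 30 lists with enough members, 17 had a median outside the central 95% of 10000 expression-matched random lists. The medians of the white adipocyte, beige precursor, DNA methylation, RNA methylation, progenitor, depot-patterning, mesothelial, macrophage, insulin and glucose, Wnt and BMP, circadian, corticosteroid receptor and Hippo lists lay inside it. Lists of unrelated genes would give 1.5 outside, but members of a list may vary together, so 1.5 is no chance rate for them. Between PDGFRα+ PBS and the PDGFRα+ DEX column of the between-type table, only 21 genes apart, 12 lists lay outside. With the other CD137+ DEX column, set across tables, 1482 genes were 2-fold apart. There 24 of 26 adipocyte genes and 14 of 32 glucocorticoid-induced genes were 2-fold lower, and the interferon median turned to -2.93 with 26 of 27 genes lower and the mural median to 0.84 with 5 of 11 higher. The cell cycle median was 1.251 there, with 22 of 33 genes 2-fold higher. The inflammatory list then had 9 higher and 5 lower of 26 with a median of 0.008, the endothelial list none of 12 past 2-fold with a median of -0.094, and both lay inside their random range, as did the thermogenic and skeletal muscle lists. Emcn and Cdh5 turned to log2 differences of 0.78 and 0.30. The authors' deposited table gives 528 genes with q under 0.05, 256 higher and 272 lower.

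In PDGFRα+ cells, the library labelled DEX held less mRNA of adipocyte and glucocorticoid-induced genes and more of cell division genes. The complement gene C7 stood at 89.4 FPKM with PBS and 0.235 in the library labelled DEX, Saa3 at 16979 and 282, and the protease inhibitor A2m at 242 and 4.03. Cck, which encodes the peptide hormone cholecystokinin, stood at 4.21 and 768 FPKM and the BMP antagonist Grem1 at 0.225 and 29.4. The typical gene was 0.28 log2 units higher in the library labelled DEX. As deposited, 2049 genes were at least 2-fold higher and 1016 lower among 13181, and relative to that shift 1301 were higher and 1470 lower. List medians and member counts for this table are given relative to the shift.

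Of 32 glucocorticoid-induced genes 22 were 2-fold lower and none higher, with a median of -1.27. Besides Tsc22d3, Zbtb16 and Klf15 these include Agt, which encodes angiotensinogen (45.7 and 3.98 FPKM), and the sulfotransferase Sult1a1 (51.5 and 2.57). Hsd11b1, which regenerates active glucocorticoid inside cells, stood at 241 and 21.96 FPKM, and Nr3c1 at 30.5 and 17.6. Of 17 circadian clock genes 8 were lower (median -0.83), such as the output gene Dbp (11.1 and 1.66 FPKM).

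Adipocyte genes were lower too. Of 25 general adipocyte genes 16 were 2-fold lower and 1 higher (median -1.15), with the fatty acid carrier Fabp4 at 738 and 66.5 FPKM, the retinol carrier Rbp4 at 37.4 and 1.38, Adipoq at 14.7 and 1.44 and Pparg at 7.68 and 2.29. Of 18 white adipocyte genes 9 were lower and 1 higher (median -0.89), including the matrix gene Dpt (106 and 4.11 FPKM). Lipogenesis genes had 7 of 21 lower (median -0.58), lipolysis and fatty acid oxidation genes 3 lower and 1 higher of 18 (median -0.40), and thermogenic genes 4 lower and 2 higher of 13 (median -0.77). G0s2, an inhibitor of triglyceride lipase, stood at 168 and 4.64 FPKM. The deiodinase gene Dio2 went the other way (0.227 and 4.99 FPKM), and Ucp1 was not listed.

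Progenitor and matrix genes had medians below that of the table. Of 22 progenitor markers 10 were lower and 1 higher (median -0.73): Pdgfra stood at 136.7 and 57.9 FPKM, Cd34 at 29.97 and 5.56, and the proteoglycan Dcn at 1183 and 248, against Cd24a at 29.3 and 198. Of 34 matrix genes 15 were lower and 7 higher (median -0.88), with collagen Col6a1 at 405 and 47.6 FPKM and the collagenase Mmp13 at 0.195 and 18.2. Tnfrsf9, the gene of CD137, stood at 4.14 and 1.62 FPKM.

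Cell cycle genes were the most uniform group on the higher side. Of 33 members 29 were 2-fold higher and none lower (median 1.51), including Cdc20 (2.94 and 23.9 FPKM), the mitotic cyclin Ccnb1 (5.07 and 29.2) and the replication licensing factor Mcm5 (1.59 and 14.1). Of 22 cholesterol synthesis genes 9 were higher (median 0.80). Of 38 oxidative phosphorylation subunits 4 were higher (median 0.26), with cytochrome c, Cycs, at 7.66 and 38.9 FPKM. Mitochondrially encoded genes took 3.63% of FPKM with PBS and 7.80% in the library labelled DEX. Tead1 differed little (45.3 and 61.1 FPKM), while the TEAD targets Ctgf (109 and 598) and Ankrd1 (5.47 and 51.6) were higher and the ectonucleotidase Nt5e lower (57.5 and 9.20). The whole Hippo list had 6 of 37 higher and 2 lower. In the DNA methylation list 3 of 21 were higher and 2 lower (median -0.41), with the maintenance factors Uhrf1 (1.59 and 12.5 FPKM) and Dnmt1 (5.59 and 16) among the former. None of 18 RNA methylation genes passed 2-fold.

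Markers of other cells lay in both directions. Of 15 mesothelial markers 6 were higher and 5 lower, with the keratins Krt8 (18.2 and 205 FPKM) and Krt18 (17.3 and 159.6) and the cadherin Cdh1 (2.24 and 45.1) on one side and Wt1 (44.2 and 15.9) on the other. Of 14 mural and smooth muscle markers 4 were higher, led by the smooth muscle actin Acta2 (507 and 1808 FPKM). Of 12 endothelial markers 4 were lower and 1 higher (median -0.92). Inflammatory genes split, 8 higher and 6 lower of 26, as in Ptgs2 (15.4 and 123 FPKM) and Il33 (84.5 and 6.11). Interferon response genes had 5 lower and 2 higher of 26 (median -0.52), Ifit3 and Ifit3b, near-identical copies whose values are uncertain, being the higher ones.

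Of the 30 testable lists 17 lay outside their random range. With the other PDGFRα+ DEX column, set across tables, 21 genes of 12456 were 2-fold apart, 0 of 32 glucocorticoid-induced genes and 0 of 26 adipocyte genes passed 2-fold, and the medians of both lists turned to 0.02 and 0.17. The authors' deposited table gives 2251 genes with q under 0.05, 1406 higher and 845 lower.

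**Figure D3:**
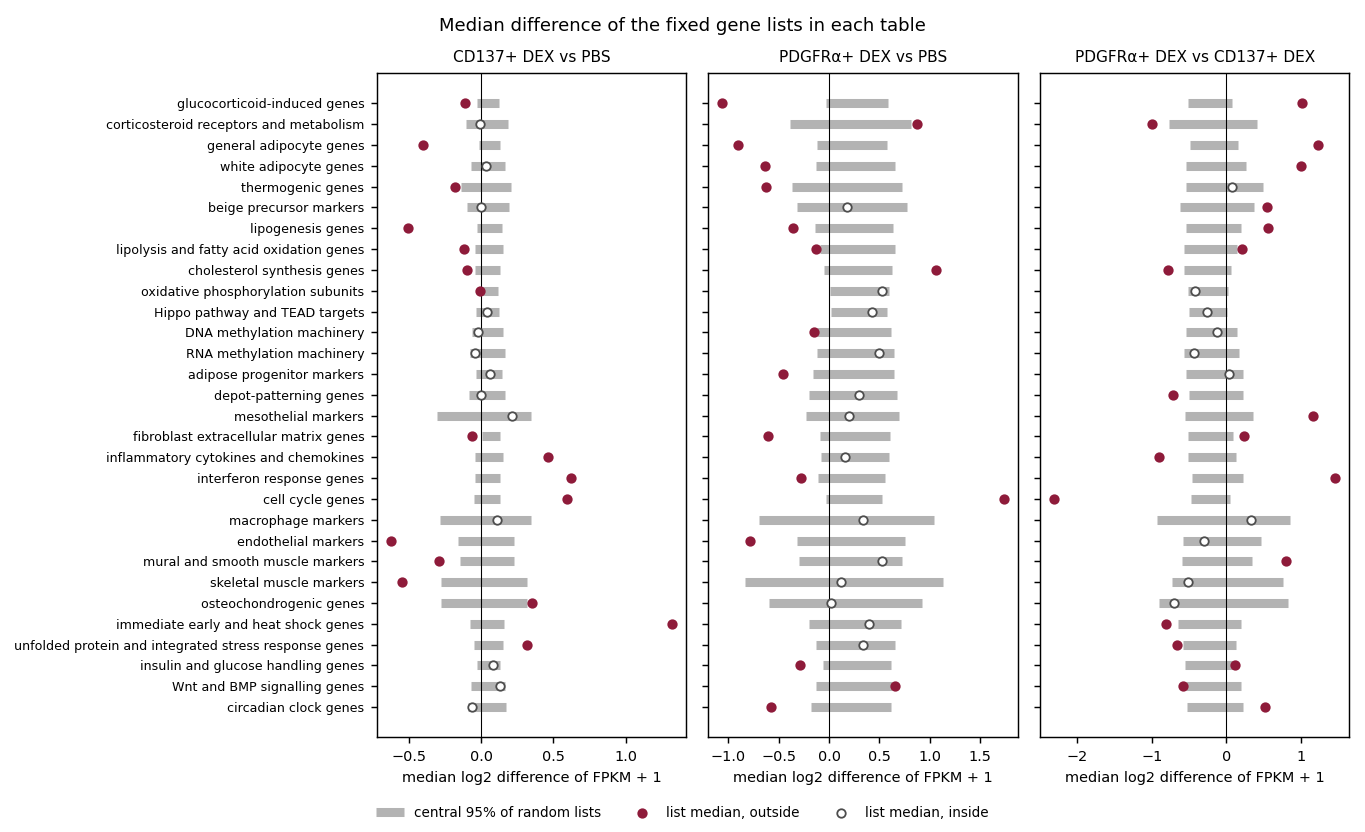
Median log2 difference of FPKM + 1 (x axis) of the 30 testable gene lists (y axis) in the 3 deposited comparisons, with grey bars for the central 95% of 10000 expression-matched random lists; filled points lie outside it. The glucocorticoid-induced list lies at -0.11, -1.06 and 1.02 and the cell cycle list at 0.59, 1.73 and -2.32 on the deposited scale. With the other DEX columns both turn sign in the second panel, only to 0.02 and -0.06, and in the third panel.

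Between the cell types in the between-type table, the PDGFRα+ library labelled DEX held more mRNA of glucocorticoid-induced, adipocyte and interferon response genes, and the CD137+ library labelled DEX more of dividing cells. A2m stood at 0.759 FPKM in the CD137+ and 266 FPKM in the PDGFRα+ library, C7 at 0.0308 and 125, and the carbonic anhydrase Car3 at 0.0483 and 76.5. The interleukin-33 receptor Il1rl1 stood at 83.5 and 0.241 FPKM, Cck at 195 and 2.30, and Grem1 at 50.2 and 0.233. The prolactin family genes Prl2c2 and Prl2c3 also stood at higher FPKM in the CD137+ library, but as near-identical copies their values are uncertain. The typical gene was -0.24 log2 units off, lower in PDGFRα+ cells. As deposited 1195 genes were at least 2-fold higher and 1481 lower in PDGFRα+ cells among 12912, and relative to the shift 1552 were higher and 975 lower. List values for this table are relative to the shift as well.

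Of 32 glucocorticoid-induced genes 18 were higher in PDGFRα+ cells and none lower (median 1.23), with Tsc22d3 at 28.7 and 122 FPKM and Sult1a1 at 0.927 and 64.5. Fkbp5 stood at 47.7 and 73.8 FPKM and Nr3c1 at 15.1 and 28.99. Of 26 general adipocyte genes 16 were higher and none lower (median 1.38): Adipoq stood at 0.149 and 18.9 FPKM and the hormone gene Retn at 0.0888 and 20.03, whereas Pparg stood at 14.2 and 8.05. Of 19 white adipocyte genes 11 were higher and 2 lower (median 1.13), and of 21 lipogenesis genes 8 were higher and 1 lower (median 0.79), with the desaturase Scd1 at 86.2 and 355 FPKM. Of 25 interferon response genes 20 were higher and none lower (median 1.64), with the antiviral tetherin gene Bst2 at 13.02 and 89.8 FPKM. Beige precursor markers had 5 higher and 1 lower of 12 (median 0.77), Tnfrsf9 being higher in the PDGFRα+ library (0.161 and 4.81 FPKM). That list also holds Pdgfra, the sorting marker of the PDGFRα+ cells (67.7 and 146 FPKM), and the mural gene Myh11 (4.97 and 26.7). Both were among the 5 higher, so the count is no measure of beige precursors alone.

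On the other side, 32 of 33 cell cycle genes were lower in PDGFRα+ cells (median -2.10), with Cdc20 at 33.5 and 2.66 FPKM. Of 22 cholesterol synthesis genes 2 were lower (median -0.55). Inflammatory genes had 10 lower and 7 higher of 27 (median -0.69), with Ccl2 at 365 and 49.9 FPKM and Saa3 at 434 and 22241. Immediate early and heat shock genes had 5 lower and 1 higher of 15 (median -0.58), with Egr1 at 104 and 10.2 FPKM. Pdgfra stood at 67.7 and 146 FPKM. Tead1 differed little (42.6 and 40.9 FPKM), and the Hippo list had 4 higher and 4 lower of 37.

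Some genes of position in the body differed between the cell types. Tbx15, a developmental factor known from subcutaneous fat, stood at 36.2 FPKM in the CD137+ and 0.630 FPKM in the PDGFRα+ library, and Shox2 at 13.6 and 0.138. Wt1 (1.73 and 39.01 FPKM) and Tcf21 (0.640 and 81.1), known from visceral fat, were on the PDGFRα+ side. The depot-patterning list as a whole had 5 of 22 higher and 9 lower in PDGFRα+ cells (median -0.54), and with the other DEX columns its median turned to 0.18, inside its random range. Of 15 mesothelial markers 12 were higher in PDGFRα+ cells and none lower (median 1.28), such as Msln (1.21 and 15.2 FPKM), and of 14 mural markers 7 were higher (median 1.02), such as desmin, Des (5.68 and 103). Matrix genes had 12 higher and 5 lower of 34, with Lum at 3.07 and 144 FPKM and Thbs2 at 610.1 and 27.8.

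Here 20 of 30 lists lay outside their random range. With the DEX columns of the other 2 tables instead, 1761 genes were 2-fold apart and many directions turned: 24 of 26 adipocyte genes, 14 of 32 glucocorticoid-induced genes and 25 of 27 interferon response genes were lower in PDGFRα+ cells, and the cell cycle median was 0.19. Of 108 named genes 2-fold apart 72 turned, among them Cck (log2 difference -5.89 in the between-type table and 5.42 with the other columns), Grem1 (-5.38 and 3.03) and Car3 (6.21 and -6.17). The authors' deposited table gives 1942 genes with q under 0.05, 987 higher and 955 lower.

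With PBS, the cell types can be set side by side only across tables, with the median difference at 0. PDGFRα+ cells then had fewer adipocyte transcripts: 21 of 26 general adipocyte genes were 2-fold lower and 1 higher (median -2.32), with Fabp4 at 1814 FPKM in CD137+ and 738 FPKM in PDGFRα+ cells, Adipoq at 145 and 14.7, and Pparg at 46.6 and 7.68. Of 27 interferon response genes 19 were lower (median -1.34), such as Isg15 (65.9 and 21.2 FPKM), and of 20 lipogenesis genes 14 were lower (median -1.76). Of 13 mural markers 9 were higher (median 1.72), such as Des (1.83 and 113 FPKM), and of 32 glucocorticoid-induced genes 12 were higher and 4 lower. Tbx15 stood at 55.5 and 0.946 FPKM. In all, 1029 genes were 2-fold higher and 672 lower in PDGFRα+ cells among 12481.

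Within the CD137+ and PDGFRα+ tables, the differences between the libraries labelled DEX and PBS had little in common between the cell types. Across 12862 genes their Pearson r was 0.095 and Spearman's rho 0.066, and 53.4% of genes had the same sign. Of genes past 2-fold in both tables, 15 were higher in both and 16 lower in both, against 7.65 and 4.87 for independent lists. Both counts exceeded those for independent lists, and the genes lower in both include structural RNAs such as Rmrp and Rn18s-rs5. Another 19 went opposite ways, for which no such count was computed, so whether there was a shared direction was not settled. The tables shared no library. With the DEX columns of the between-type table, set across tables, r turned to -0.087. With the CD137+ DEX column of the between-type table and the PDGFRα+ DEX column of the PDGFRα+ table, r was 0.562 across 12841 genes. The likeness thus depends on which DEX columns are used.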

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

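Each value here is a difference between the cell types that was not tested, since the labels give 1 sample per group: the library labelled DEX lay to one side of PBS in CD137+ cells and to the other in PDGFRα+ cells. Values are on the deposited scale, so the shift of 0.28 in the PDGFRα+ table is part of each, and those with the other DEX columns were set across tables. Cholesterol synthesis genes had a median log2 difference of -0.10 in the CD137+ table and 1.07 in the PDGFRα+ table, 1.16 apart, and -0.27 and 0.11 with the other DEX columns. Interferon response genes had medians of 0.62 and -0.28, which are -0.90 apart, and both turned with the other DEX columns, to -2.93 and 0.14. The immediate early gene Fos had log2 differences of 5.03 and -1.17, -6.21 apart, and 4.51 and -0.086 with the other DEX columns. The keratin gene Krt8 had -1.39 and 3.42, 4.81 apart, but 1.16 and 0.23, both above 0, with the other DEX columns. The structural RNA Rn7sk had -3.31 and 1.30, 4.61 apart, but was below PBS in both other DEX columns (15.01 and 4.39 FPKM in CD137+ cells, 7.57 and 2.37 in PDGFRα+ cells), and Rmrp, Rpph1, Rn7s1, Rn7s2 and Rn18s-rs5 were lower with DEX in both tables. The skeletal actin gene Acta1 had -1.10 and 2.06, 3.16 apart, and both turned with the other DEX columns, to 0.49 and -0.047. The stress response gene Trib3 had 1.82 and -1.32, -3.14 apart, and 1.62 and -0.31 with the other DEX columns. Id3, a target of BMP signalling, had 1.02 and -1.04, -2.06 apart, but its levels in PDGFRα+ PBS and the other PDGFRα+ DEX column were 173 and 179 FPKM.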

How the results depend on the processing

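The exchange of DEX columns between tables, the rescaled member counts of lists and all alternatives to the difference of DEX differences were chosen after seeing the data; the other alternatives were planned. The count of genes 2-fold apart in the CD137+ table (128) was 375 and 46 with pseudocounts of 0.1 and 5 FPKM, 55 with a minimum of 10 FPKM, 696 and 19 at 1.5-fold and 4-fold, and 426 by the authors' deposited log2 ratio. In the PDGFRα+ table (3065) it was 1338 with a pseudocount of 5 FPKM, 1812 with a minimum of 10 FPKM, and 6233 and 526 at 1.5-fold and 4-fold. In the between-type table (2676) the same settings gave 1222, 1581, 5745 and 571. The other planned settings left these counts, and each count of lists outside their range, within 1.5 times. Part of this was fixed beforehand. With 1 FPKM added, no gene under 1 FPKM in both libraries can reach 2-fold, so dropping the minimum changed nothing. Setting the median difference to 0 moves a list and its random lists nearly alike. With the DEX columns exchanged the counts became 1482, 21 and 1761. The difference of DEX differences (2853 genes) became 1624, and the correlation of the DEX differences turned from 0.095 to -0.087; the cause was not tested.

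The exchange also reversed 25 of the list medians that lay outside their random range and at least 0.1 from 0, and the cause was not tested. In the CD137+ table the interferon median became -2.93 and the mural 0.84. In the PDGFRα+ table the glucocorticoid-induced median became 0.0203, general adipocyte 0.17, white adipocyte 0.0407, lipogenesis 0.0703, lipolysis 0.10, progenitor 0.12, interferon 0.14 and cell cycle -0.0617. There the other column was 21 genes from PBS, so such a turn is mostly the sign of a small remaining difference. The glucocorticoid-induced, white adipocyte, lipogenesis and cell cycle medians then lay inside their random ranges. In the between-type table glucocorticoid-induced became -0.83, corticosteroid receptors 0.43, general adipocyte -3.29, white adipocyte -0.94, beige precursor -0.32, lipogenesis -1.69, lipolysis -0.89, cholesterol 0.099, depot-patterning 0.18, matrix -0.71, interferon -2.40, cell cycle 0.19, insulin and glucose -0.32, Wnt and BMP 0.55 and circadian -0.82. Of lists outside their range, 11 of 17, 3 of 17 and 3 of 20 stayed outside it on the same side. Of named genes 2-fold apart, the direction turned for 5 of 32, 53 of 116 and 72 of 108 in the 3 tables. Those that stayed 2-fold apart in the same direction were 24, 0 and 17. Under the planned settings none of those list medians changed direction. No named gene past 2-fold did either, but this could not have come out otherwise. A pseudocount, minimum or threshold cannot turn a difference, and rescaling moved genes by 0.295 log2 units at most. Of 782 recomputed differences of named genes 82 moved by 1.5-fold or more, of 270 list medians 71 moved by more than their spread without reversing, and of 540 member counts 193 moved by more than 1.5 times. The numbers in the sheet titles join PBS to 1 DEX library per cell type, and these contrasts gave 126 and 21 genes 2-fold apart with the median at 0. No paired test was made, since each cell type has 1 such pair. Depth is unknown, so the counting error of low genes could not be given.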

Other observations

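Every test in the paragraphs on the 3 patterns was chosen only after the result it bears on was seen, except that of gene length and GC content.

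Sfrp2, Mgp and desmin (Des) stood apart by cell type in all 6 libraries. Sfrp2, a secreted modulator of Wnt signalling, stood at 278, 279 and 55.7 FPKM in the CD137+ libraries and at 13.3, 2.81 and 12.7 FPKM in the PDGFRα+ libraries. Mgp, a matrix protein that blocks calcification, stood at 18.2, 22.7 and 36.6 FPKM and at 651, 255 and 963 FPKM. Desmin stood at 1.83, 1.31 and 5.68 FPKM and at 113, 128 and 103 FPKM. In the PDGFRα+ table Wnt and BMP signalling genes had 6 of 23 higher and 4 lower in the library labelled DEX, with Inhba, an activin subunit, at 17.1 and 107 FPKM and Sfrp1 at 502 and 71.1. Insulin and glucose genes had 6 of 26 lower and 2 higher there, with the binding protein Igfbp4 at 247 and 25.7 FPKM. Corticosteroid receptor and metabolism genes had 2 higher and 2 lower of 10. Stress response genes had 1 higher and 4 lower of 20, beige precursor markers 1 higher and 4 lower of 12, and depot-patterning genes 2 lower of 17. Osteochondrogenic genes had 2 higher and 1 lower of 6, with the matrix phosphoprotein Spp1 at 140.5 and 2151 FPKM. In the CD137+ table the median of 5 osteochondrogenic genes was 0.35. Macrophage markers had 1 of 4 higher in the PDGFRα+ table, and skeletal muscle markers 1 higher and 1 lower of 4.

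The first pattern is that columns labelled DEX hold different values in different tables. A single library rescaled in each table is argued against by a log2 ratio whose SD across genes was 0.57 for CD137+ and 0.78 for PDGFRα+, and an exchange of cell types in only 1 table by a score of Tbx15, Shox2 and Hoxc10 against Wt1 and Tcf21 (genes not listed taken as 0), which kept a gap of 6.74 between the lowest CD137+ and the highest PDGFRα+ library. An exchange of the labels of cell type in every table stays open, since Tnfrsf9 was lower in the CD137+ libraries. Within the PDGFRα+ table, more mesothelial cells are argued against by 5 markers that were 2-fold lower beside 6 higher, and length and GC bias by a glucocorticoid-induced median that was still -1.24 after their correction. What stays open for that table's DEX column, whose library number differs from that of PBS, is a separate culture without glucocorticoid (median of glucocorticoid-induced genes -1.27, against 0.02 in the other column). A less differentiated culture stays open too (median of adipocyte genes -1.15, against 0.17). A wrong label may lie behind either, on the DEX column, on PBS or on both by exchange. PBS itself was 21 genes from the other column labelled DEX. Glucocorticoid-induced genes did not rise as a list, but a less differentiated culture could lower them as well. That list shares Agt with the white adipocyte list and Lpin1 with the lipogenesis list. The -1.27 thus cannot decide on induction of known targets by DEX, and another response to DEX stays open as untested.

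The second pattern is the higher immediate early genes beside lower structural RNAs in the CD137+ library labelled DEX. They did not go together in every contrast. In the PDGFRα+ DEX column of the between-type table, Rn18s-rs5 was lower than with PBS (2086 FPKM with PBS and 167 with DEX). Rmrp was lower there too (5.44 and 0.245), but Fos was level (43.7 and 42.1). The glucocorticoid-induced list did not rise as a whole. Its median of -0.11 lay at percentile 0 of its random lists (range -0.03 to 0.13), though 1 member, Dusp1, was 2-fold higher. General adipocyte genes were lower too (median -0.40), and the list shares Agt and Lpin1 with the white adipocyte and lipogenesis lists. The percentile thus cannot decide on induction of glucocorticoid targets. Both CD137+ DEX columns lay above PBS at Fos (3.54 FPKM with PBS, 148 and 112 FPKM), but against the same PBS library, so a PBS library low in these genes stays open. Carry-over of structural RNA that rescales all messenger RNA alike is argued against for the immediate early and heat shock genes, whose median lay 1.27 above that of the table. It stays open for the structural RNAs. Handling of the cultures before lysis stays open and was not tested.

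The third pattern is that the between-type comparison resembles the PDGFRα+ table with its direction turned. Part of this likeness follows from the PDGFRα+ DEX column of the between-type table, which is 21 genes from PDGFRα+ PBS. A candidate explanation for the rest is that the CD137+ DEX column of the between-type table shares the state of the PDGFRα+ DEX column of the PDGFRα+ table, from which it was 867 genes apart. The differences of these 2 columns from the PBS library of their own cell type, made of 4 separate columns, had a Pearson r of 0.562 across 12841 genes, so this stays open. The cell types as seen with PBS ran the other way for general adipocyte (median -2.32, against 1.38 in the between-type table), lipogenesis (-1.76 against 0.79), lipolysis (-0.77 against 0.44), interferon (-1.34 against 1.64) and Wnt and BMP genes (0.88 against -0.37). This argues against them for these lists. They stay open for the rest, some of which ran the same way, such as mesothelial (2.07 and 1.28), mural (1.72 and 1.02) and cell cycle genes (-0.72 and -2.10). The 2 differences had an r of 0.564 across 12800 genes. As 1 holds PDGFRα+ PBS and the other its near copy, this r cannot decide.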
